A study of Arabidopsis thaliana with 6 samples.

How the data were processed

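Total RNA of whole Arabidopsis seedlings aged 8 days was sequenced in 6 libraries, 3 of the wild type and 3 of phod2, which the study describes as biological replicates. Groups and replicate numbers were taken from the sample labels. The labels mention high and low phosphate supply for the series as a whole and do not name the supply of a library, so supply entered no test. The aligner, the counting program and the use of strand are not given in the sources used here. The submitters' processing notes name the genome build mm10, a mouse build, which does not match the Arabidopsis gene identifiers and coordinates of the table.

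The deposited table holds 32833 genes with whole-number counts per library, per the file headers, and 7347 of them were at 0 in all libraries. It also holds FPKM per library, per the file headers. The deposited FPKM equal the count divided by the exonic gene size and the library total, on the usual scale of FPKM, to within 0.005, the rounding of the file, so they carry no scaling beyond library totals. The exonic gene sizes are a further deposited column in bases. Of the 32833 identifiers 32548 were found in the TAIR10.1 annotation, and 32520 of these (99.9%) had the same start and end there. Coordinates are those of the table, counted from 1.

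Library totals were 22417595, 17319308 and 21639995 counts in WT replicates 1 to 3 and 17996741, 19375445 and 20951575 in phod2 replicates 1 to 3. Libraries of one genotype differed by more than sampling noise (chi-square per degree of freedom 1.57 to 2.07) and those of different genotypes by far more (21.7 to 25.7). No library was thus a copy of the reads of another. These values cannot tell separate plants from separate preparations of a single pool of plants. The first principal component held 78.3% of the variance and separated the genotypes. The common biological coefficient of variation was 2.83%. P-values measure the spread between these libraries, and where plants of one group were grown together that spread can be smaller than between separate experiments.

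Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, 2-sided) in R 4.3.3, after filterByExpr left 20169 genes, with TMM factors of 0.985 to 1.017 and genotype as the only term. The planned design named limma on log2(FPKM + 1) unless counts were present, which they were. A gene was called at a Benjamini-Hochberg adjusted p of 0.05 or less and at least a 2-fold change, the rule stated by the study. The standard error is the absolute log2 fold change divided by the square root of the F statistic. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 22 lists, and again with an estimated correlation. The lists were fixed from general knowledge before the data were examined, except that the plastid-encoded and mitochondrion-encoded lists were taken by identifier. Gene Ontology terms of the table with 10 to 500 tested genes were tested by one-sided Fisher's exact test against the 13496 tested genes that carry a term. Counts were simulated with 200 genes changed, up and down alike, and a spread set by the dispersion trend, and 19942 genes were tested. By the adjusted p alone, the edgeR step recovered 86.2% of genes changed 1.5-fold, 94.0% at 2-fold and 100% at 4-fold. Of the genes past it, 5.15% were unchanged. Many more genes differ in the data, and most called genes are lower, so these rates need not hold there or for the 2-fold rule.

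Named genes follow a rule set before the data were examined. They are LIP1P, the 12 genes with the largest fold change in each direction among called genes with separate groups and at least 5 FPKM in the higher group, 12 phosphate genes fixed by name, and up to 4 members with the lowest adjusted p of each list with a called member. Genes named outside it are said to be. Transcripts of the named genes were compared with all other transcripts of TAIR10.1 by blastn (BLAST 2.17.0), and matches of at least 95% identity over at least 30% of the transcript, or an overlap of over 25% with another gene, are stated beside the gene. Overlaps were found from the gene coordinates with pandas 2.3.3 and tested with scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Alternatives were DESeq2 1.42.0, other scalings, filters and pseudocounts, limma on log2 FPKM, a replicate block, each library left out in turn and other Gene Ontology settings. Library totals without TMM and a test against 2-fold (glmTreat) were added after the data were seen.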

Results

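Messenger RNA levels were measured by RNA sequencing in whole Arabidopsis thaliana seedlings aged 8 days, in 3 libraries of the wild type (WT) and 3 libraries of the phod2 mutant. The libraries held 17319308 to 22417595 counted reads, and 20169 genes had enough counts to be tested. The series title ties the study to LIP1p, a lipoyl synthase of the plastid, and to phosphate homeostasis, so the comparison of phod2 with WT asks which transcripts differ in the mutant. The study mentions seedlings from high or low phosphate supply, and the labels of the single libraries do not name the supply. All fold changes below are phod2 relative to WT.

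LIP1P (AT5G08415, chromosome 5, positions 2710781 to 2713255, minus strand), the gene of the plastidial lipoyl synthase, had a lower transcript level in all 3 phod2 libraries. Its counts were 769, 558 and 773 in WT and 387, 425 and 417 in phod2, or 22.1 ± 1.14 against 13.7 ± 0.690 FPKM (SD, n = 3 each). The log2 fold change was -0.74 ± 0.06 (SE, adjusted p = 4.7e-15), short of the 2-fold rule. The annotated transcript has 7 exons and 1541 bases. The counts cover the whole gene, so a mutation that leaves the transcript in place would not show in them. The descriptions of the phod2 libraries name LIP1 in place of phod2. The labels do not say what kind of change phod2 carries.

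The lists of phosphate starvation, iron homeostasis and membrane lipid remodelling genes were shifted upward in phod2, and those of root hair and endodermis markers downward. The root hair list missed the threshold with an estimated correlation (adjusted p = 0.064). With the preset correlation, 1 to 6 lists also passed in splits of the libraries that mixed the genotypes. Genes annotated to the cell wall were enriched among the genes lower in phod2. With edgeR, 362 genes were at least 2-fold higher and 1153 at least 2-fold lower at an adjusted p of 0.05 or less. The adjusted p alone was passed by 4214 higher and 4958 lower genes, 45.5% of those tested. In DESeq2 7415 genes passed it. Among the named genes with the largest rise were AT5G53048 (log2 fold change 4.55 ± 0.20, SE), AT5G20790 (4.06 ± 0.15), the pyrophosphatase gene PPsPase1 (3.92 ± 0.16), the acid phosphatase gene PAP17 (3.42 ± 0.08), the glycerol-3-phosphate transporter gene G3Pp1 (3.33 ± 0.09) and IMA2 (3.32 ± 0.26), which encodes a peptide of the iron deficiency response. The largest falls by the same rule were in AGP30, an arabinogalactan protein gene (-5.06 ± 0.16, from 18.7 to 0.573 FPKM), AT5G23840 (-4.63 ± 0.26, and -5.46 without phod2 replicate 3), AT1G45015 (-4.49 ± 0.27), AIR1 (-4.22 ± 0.10), AT5G46890 (-4.05 ± 0.10) and MLP328 (-4.02 ± 0.05, from 253.7 to 16.0 FPKM). They were followed by AT3G23510 (-3.85), AT5G46900 (-3.70), ROSY1 (-3.69), AT3G59930 (-3.58), AT4G12510 (-3.47) and BAHD1 (-3.30). The 3 libraries of one genotype all lay above those of the other for 1491 of the 1515 called genes, and for 54.1% of all tested genes where chance gives 10%. The number called was 138 higher and 489 lower by limma on log2(FPKM + 1), where the added pseudocount shrinks folds of low genes (over the limma fits to as little as -3.58 for AGP30, -2.57 for AT5G23840 and 2.86 for AT5G53048), and 147 and 596 when edgeR tested against a 2-fold change, an alternative chosen after the data were seen. AT5G53048 and AIR1 lie 88.2% and 92.9% within other genes, and AT3G23510 and AT3G59930 have near-identical copies, so their values are uncertain.

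**Figure D1:**
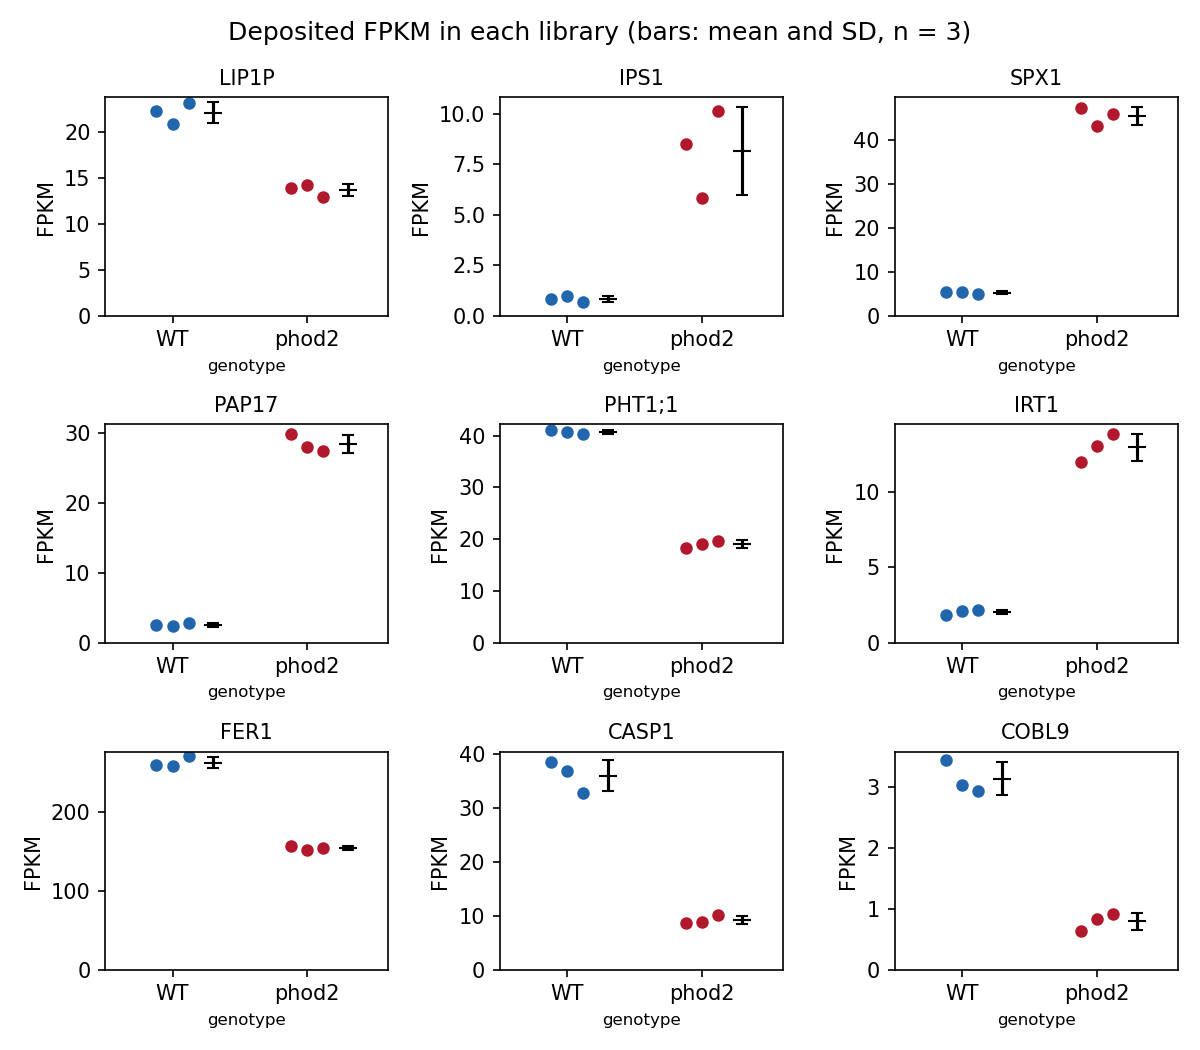
FPKM of 9 genes (vertical axes, from 0) in each of the 6 libraries, WT in blue and phod2 in red, with the mean and SD of the 3 libraries of each genotype in black. In each panel the 3 libraries of one genotype lie above the 3 of the other; SPX1 went from 5.21 to 45.5 FPKM and CASP1 from 36.0 to 9.22 FPKM.

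Genes known to be induced by phosphate starvation rose in phod2. Of 30 genes in the list, 22 were measured, 15 rose, 1 fell and 6 did not pass the test, and the counts adjusted over the list alone were the same. The glycerophosphodiester phosphodiesterase gene GDPD1 rose from 8.78 ± 0.867 to 79.6 ± 3.63 FPKM (SD, n = 3 each), a log2 change of 3.14 ± 0.05. SPX1, which encodes a phosphate sensor protein, rose from 5.21 ± 0.304 to 45.5 ± 2.05 FPKM, PAP17 from 2.56 ± 0.289 to 28.4 ± 1.28 FPKM, and the non-coding RNA IPS1 from 0.82 ± 0.14 to 8.15 ± 2.18 FPKM. SPX3 rose by 2.68 ± 0.45 on the log2 scale (adjusted p = 1.1e-06) from a low level of 0.2 FPKM, and by as little as 0.93 over the limma fits, under 2-fold. The member that fell was WRKY75 (log2 fold change -1.71 ± 0.22), named here after its value was seen. The list as a whole was shifted upward against all other genes (median log2 fold change 0.97, camera adjusted p = 2.1e-28, adjusted p = 0.0052 with an estimated correlation). GDPD1 is overlapped over 36.9% of its length by another counted gene.

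Phosphate transporter and regulator genes moved in both directions. Of 36 measured members, 4 rose (SPX2 and, named after their values were seen, PHT2;1, PHT4;4 and PHT4;5), 13 fell and 19 did not pass the test (camera adjusted p = 0.39). PHT1;1, a high-affinity uptake transporter of the root, fell from 40.6 ± 0.340 to 19.0 ± 0.699 FPKM (log2 fold change -1.14 ± 0.05, adjusted p = 2.2e-30), and PHO1, which exports phosphate to the xylem, fell from 38.3 ± 0.564 to 21.9 ± 0.682 FPKM (-0.85 ± 0.04). PHT4;1, a transporter of the chloroplast, fell by 0.65 ± 0.06 on the log2 scale. By contrast PHT1;4, another uptake transporter and a member of the starvation-induced list, rose by 1.43 ± 0.09, and SPX2 rose by 0.81 ± 0.08. PHO2, the ubiquitin conjugase that limits phosphate uptake, had a log2 fold change of -0.18 ± 0.03 (adjusted p = 4.4e-06). PHR1, the central transcription factor of the response, had -0.02 ± 0.05 (adjusted p = 0.806), and the ubiquitin ligase gene NLA had -0.04 ± 0.08 (adjusted p = 0.758). In the same libraries the root hair marker list had a median log2 fold change of -1.59. PHT1;1 shares 97.7% identity over 78.4% of its transcript with AT5G43370, so its value is uncertain where reads match both.

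Genes that replace membrane phospholipids by galactolipids and sulfolipids rose. Of 12 measured members 9 rose, none fell and 3 did not pass the test (median log2 fold change 0.44, camera adjusted p = 1.0e-09, adjusted p = 0.026 with an estimated correlation). The sulfolipid gene SQD1 rose from 39.5 ± 0.701 to 91.6 ± 0.817 FPKM (log2 fold change 1.17 ± 0.03) and SQD2 from 32.1 ± 0.927 to 51.2 ± 1.27 FPKM (0.63 ± 0.04). The galactolipid synthase gene MGD3 rose from 0.777 ± 0.0513 to 7.64 ± 0.599 FPKM (3.25 ± 0.14), and MGD2 rose by 1.37 ± 0.09.

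Members of the iron homeostasis list moved in both directions, and more of them rose than fell. Of 30 measured iron homeostasis genes, 19 rose, 8 fell and 3 did not pass the test. The iron transporter gene IRT1 rose from 2.03 ± 0.159 to 13.0 ± 0.909 FPKM (log2 fold change 2.64 ± 0.11, adjusted p = 6.1e-29) and the ferric reductase gene FRO2 rose from 0.643 ± 0.170 to 5.91 ± 0.443 FPKM (3.12 ± 0.14). FER1, a ferritin that stores iron in plastids, fell from 263.2 ± 7.14 to 154.7 ± 2.59 FPKM (-0.81 ± 0.03). PDR9, a transporter that secretes coumarins, fell by 0.87 ± 0.04 on the log2 scale. The list members CYP82C4 and S8H, looked up after the values were seen, rose by 4.31 ± 0.24 and 6.58 ± 0.60. Both were low in WT, at 0.187 and 0.01 FPKM. FER2, FER3 and FER4, looked up after the values were seen, had log2 fold changes of -0.56, -0.62 and -0.36 with adjusted p of 0.0389, 2.8e-22 and 2.5e-10. The list was shifted upward (median log2 fold change 0.67, camera adjusted p = 5.5e-05, adjusted p = 0.049 with an estimated correlation), a call lost when only genes at 5 FPKM or more in 3 libraries were kept (adjusted p = 0.109). FER1 is overlapped over 63.5% of its length by another gene.

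**Figure D2:**
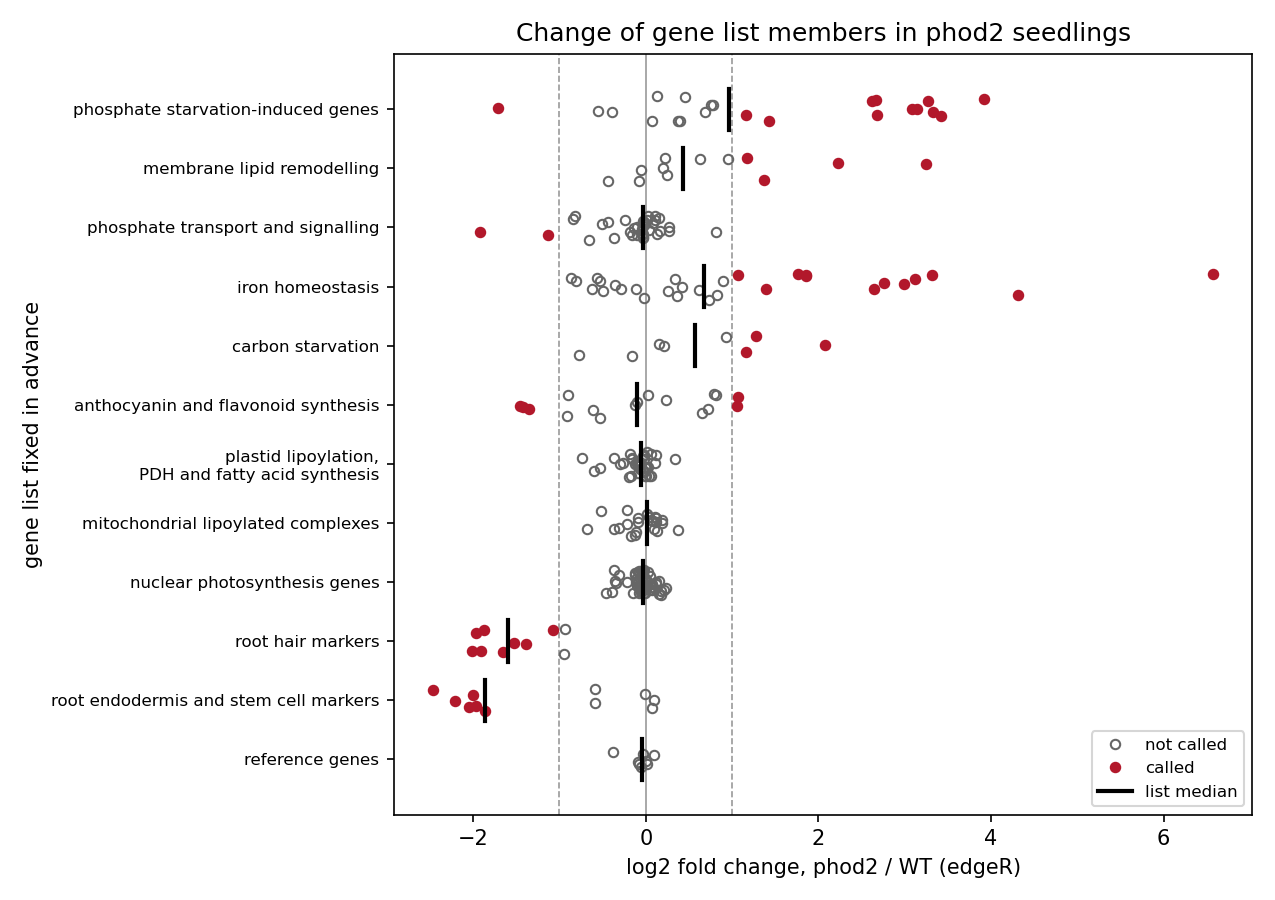
Log2 fold change of phod2 over WT (horizontal axis) for the measured members of 12 of the gene lists fixed in advance (rows). Filled red points are genes called at 2-fold and an adjusted p of 0.05, open points are the other members, black bars are list medians and dashed lines mark 2-fold. Members of the phosphate starvation list lie mostly to the right (median 0.97) and the root hair list lies wholly to the left (median -1.59).

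Genes of lipoylation, fatty acid synthesis and photosynthesis changed by less than 2-fold where they changed. In the list of plastid lipoylation, pyruvate dehydrogenase and fatty acid synthesis genes, 38 members were measured, 2 rose (SSI2 and PKPB1, named after their values were seen), 14 fell, 22 did not pass the test, and edgeR and DESeq2 each called 0 at 2-fold (17 had an unadjusted p under 0.05 in edgeR, lowest adjusted p 4.7e-15, for LIP1P itself). The median log2 fold change was -0.06 (camera adjusted p = 0.355). Mitochondrial lipoylated complexes had 23 measured members, of which 8 rose and 9 fell, with 0 called at 2-fold by either tool, 18 at an unadjusted p under 0.05 in edgeR and a lowest adjusted p of 2.7e-18; their median log2 fold change was 0.01 while camera placed them downward (adjusted p = 0.876). Of 54 nuclear photosynthesis genes 13 rose and 23 fell, and of 18 chlorophyll synthesis genes 8 rose and 4 fell, again with 0 called at 2-fold by either tool, 38 and 12 at an unadjusted p under 0.05 in edgeR, and lowest adjusted p of 3.6e-23 and 8.0e-14. The log2 fold changes of the photosynthesis genes spanned -0.47 to 0.23 (camera adjusted p = 0.527) and the camera adjusted p of the chlorophyll list was 0.671.

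Counts of plastid-encoded genes rose where they passed the test. These genes took 0.0312% to 0.0343% of the counts in WT and 0.0453%, 0.0486% and 0.0364% in phod2 replicates 1, 2 and 3. Shares this small may not follow the level of plastid transcripts, which was not tested. Of 70 measured members 25 rose and none fell in edgeR, and 10 passed the adjusted p in DESeq2 (camera adjusted p = 0.016, adjusted p = 0.62 with an estimated correlation and 0.0636 in DESeq2). RBCL rose by 0.71 ± 0.10, PSBA by 0.60 ± 0.09, PSAA by 0.53 ± 0.11 and PSAB by 0.44 ± 0.10 on the log2 scale. PSBA had an SD of 18.0 FPKM around a mean of 55.1 FPKM in phod2, and RBCL, PSBA and PSAB missed the threshold with robust variance shrinkage (adjusted p = 0.136, 0.173 and 0.232), PSBA and PSAB also in DESeq2 (adjusted p = 0.0824 and 0.142). The log2 fold changes were 0.44 for RBCL and 0.31 for PSBA without phod2 replicate 2, and 0.35 for PSAA and 0.25 for PSAB without phod2 replicate 1, where PSAB missed the threshold (adjusted p = 0.0531).

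Root hair and endodermis markers fell in phod2. All 10 measured root hair markers fell, 8 of them at least 2-fold (median log2 fold change -1.59, camera adjusted p = 3.0e-06, adjusted p = 0.064 with an estimated correlation). LRX1, a cell wall protein gene of root hairs, fell by 1.96 ± 0.14 on the log2 scale, COBL9 by 2.01 ± 0.17, the NADPH oxidase gene RBOHC by 1.65 ± 0.11 and PRP3 by 1.53 ± 0.10. Over the limma fits the log2 fold change was as little as -1.26 for LRX1 and -1.14 for COBL9. Of 11 root endodermis and stem cell markers 7 fell and 4 did not pass the test (median -1.86, camera adjusted p = 4.7e-06, adjusted p = 0.049 with an estimated correlation). The Casparian strip genes CASP1 and CASP2 fell by 2.00 ± 0.08 and 1.96 ± 0.10 on the log2 scale, CASP1 from 36.0 ± 2.94 to 9.22 ± 0.802 FPKM, and the peroxidase gene PER64 fell by 1.86 ± 0.08.

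Gene Ontology terms of the apoplast, cell wall and root barriers were enriched among the genes lower in phod2, in the same libraries in which the root markers fell. The test gave 51 of 1283 terms by one-sided Fisher's exact test. They included extracellular region (111 of 492 tested genes, adjusted p = 4.0e-33), peroxidase activity (31 of 97, adjusted p = 1.2e-12), cell wall (59 of 419, adjusted p = 6.8e-08), xyloglucan:xyloglucosyl transferase activity (13 of 29, adjusted p = 3.2e-07), suberin biosynthetic process (8 of 15, adjusted p = 3.8e-05) and Casparian strip (7 of 13, adjusted p = 1.6e-04). Genes higher in phod2 were enriched in 8 terms, among them response to bacterium (11 of 101, adjusted p = 0.0019), cellular response to phosphate starvation (8 of 62, adjusted p = 0.0075) and iron ion homeostasis (5 of 28, adjusted p = 0.0356). Iron ion homeostasis missed the threshold without a low-count filter (adjusted p = 0.0527) and among genes at 5 FPKM or more in 3 libraries (adjusted p = 0.347 in edgeR and 0.281 in limma). Without WT replicate 1, and without phod2 replicate 2, the higher genes gave 5 terms, and with terms of 5 to 1000 genes they gave 2.

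Flavonoid genes moved in both directions. Of 17 measured members 6 rose and 7 fell (median log2 fold change -0.10, camera adjusted p = 0.0017 downward, adjusted p = 0.078 with an estimated correlation, and 0.268 by limma on FPKM). CHS, the first enzyme of the pathway, fell from 131.7 ± 3.88 to 49.2 ± 0.987 FPKM (log2 fold change -1.46 ± 0.03), FLS1, which makes flavonols, fell by 1.35 ± 0.06, PAL1 by 0.90 ± 0.03 and C4H by 0.62 ± 0.03 on the log2 scale. DFR, LDOX and TT19, which act in anthocyanin formation and were looked up after the values were seen, rose by 0.65, 0.72 and 1.05 on the log2 scale (adjusted p = 8.7e-09, 4.1e-06 and 1.8e-08). Among 8 carbon starvation genes 6 rose and 2 fell, DIN10 and, named after its value was seen, IVD (camera adjusted p = 6.3e-04, adjusted p = 0.065 with an estimated correlation, and 0.0578 by limma on FPKM). The asparagine synthetase gene ASN1 rose from 22.8 ± 0.375 to 57.0 ± 1.33 FPKM, SEN1 rose by 0.93 ± 0.03 and BCAT2 by 1.16 ± 0.12, and DIN10 fell by 0.78 ± 0.02 on the log2 scale. BCAT2 rose by as little as 0.93 over the limma fits, under 2-fold.

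Nitrate, sulfur, salicylic acid, jasmonate and stress lists had members moving in both directions and no shift past the threshold. In the nitrate list 6 of 14 rose and 5 fell (camera adjusted p = 0.797), with NIA1 up by 0.87 ± 0.03, HHO3 by 0.42 ± 0.03, and the root xylem transporter gene NRT1.5 and the transcription factor gene HRS1 at -1.24 ± 0.03 and -1.76 ± 0.07. The sulfur list had 4 of 15 up and 5 down (0.527), with GGCT2;1 at -2.03 ± 0.18, SULTR1;2 at -0.80 ± 0.05, SULTR4;2 at -0.69 ± 0.07 and SULTR4;1 at -0.49 ± 0.05. NRT1.5 and SULTR1;2 are root transporters and lay beside a median of -1.86 for the endodermis list. The salicylic acid list had 8 of 22 up and 5 down (0.527), with SARD1 at 2.11 ± 0.21, WRKY70 at 0.77 ± 0.08, WRKY18 at -1.24 ± 0.07 and EDS5 at -0.94 ± 0.11. SARD1 was at as little as 1.08 over the limma fits. In the jasmonate list 5 of 18 rose and 5 fell (0.90), with VSP1 at -1.59 ± 0.09, AOS at -0.33 ± 0.03, VSP2 at 0.56 ± 0.06 and AOC1 at 0.39 ± 0.05. The heat and oxidative stress list had 7 of 18 up and 9 down (0.527), with GSTU24 at -1.29 ± 0.07, APX1 at -0.45 ± 0.03, CAT2 at -0.37 ± 0.03 and CAT3 at 0.21 ± 0.02.

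Among 19 cell cycle genes 2 rose (CYCB1;1 and HIS4) and 5 fell (CYCB1;2, CYCB2;2, CDKB2;1, MCM2 and PCNA2), named after their values were seen, with 0 called at 2-fold by edgeR or DESeq2, 7 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0029. In DESeq2 only 2 of the 19 cell cycle genes passed the adjusted p. Of 8 measured seed maturation markers 3 rose (camera adjusted p = 0.302, and 0.0238 by limma on log2(FPKM + 1)). CRU1 rose from 0.9 ± 0.387 to 3.40 ± 0.0950 FPKM and RAB18 by 0.73 ± 0.10 on the log2 scale. PER1 had a log2 fold change of 0.62 ± 0.23 (adjusted p = 0.0259), which missed the threshold in DESeq2 (adjusted p = 0.0861) and without WT replicate 1, WT replicate 3, phod2 replicate 1 or phod2 replicate 3 (adjusted p = 0.0800, 0.0897, 0.0662 and 0.0636), and LEA76 had 0.58 ± 0.30 (adjusted p = 0.116), and passed the threshold in 9 of the limma alternatives (adjusted p = 0.0124 to 0.0489). Of 8 reference genes 3 fell and none rose, UBQ10 at -0.06, EF1A at -0.09 and GAPC1 at -0.38, named after their values were seen; on library totals UBQ10 and EF1A missed the threshold (adjusted p = 0.484 and 0.0721). The list had 0 called at 2-fold by edgeR or DESeq2, 3 at an unadjusted p under 0.05, a median log2 fold change of -0.05 and a lowest adjusted p of 8.9e-19. Of 7 mitochondrion-encoded genes 0 passed the adjusted p in edgeR or DESeq2 and 0 had an unadjusted p under 0.05 in edgeR (lowest adjusted p 0.107). The counts adjusted over the list alone equalled those over all genes except in the lists for mitochondrial lipoylated complexes (9 higher), photosynthesis (25 lower), salicylic acid (9 higher), nitrate (6 lower), cell cycle (3 lower) and plastid-encoded genes (20 higher).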

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

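The alternatives below were planned before the data were examined, except library totals without TMM and the glmTreat test. LIP1P stayed lower and past the adjusted p under all 24 of its alternatives (log2 fold change -0.74 to -0.65) and in all leave-one-out fits (-0.77 to -0.69). The phosphate starvation list (adjusted p up to 0.0052), membrane lipid list (up to 0.0265) and root endodermis list (up to 0.0487) stayed past the threshold under all 31 alternatives run for them, leave-one-out fits included. At this depth 7347 of 32833 genes had 0 counts in all libraries and 20169 had enough counts to be tested. PER1 missed the threshold in DESeq2 and in 4 of 6 leave-one-out fits, and the cause was not tested.

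Limma on FPKM, the filter at 5 FPKM and the glmTreat test called fewer genes. Both the filter and the pseudocount lower the counts. On the same 18721 genes at 1 FPKM in 3 libraries edgeR called 251 higher and 889 lower genes, and limma 272 and 815 at a pseudocount of 0.1, 187 and 647 at 0.5 and 138 and 489 at 1. Against 362 higher and 1153 lower, edgeR on genes at 5 FPKM in 3 libraries gave 88 and 422, and the glmTreat test against 2-fold gave 147 and 596. Limma on log2(FPKM + 1) gave, without a filter, 140 and 491, at 0.1 FPKM 141 and 491, at 5 FPKM 77 and 342 (and 2791 genes lower by adjusted p alone), rescaled to a common total 177 and 615, by median of ratios 132 and 527, by TMM 132 and 531, quantile normalized 149 and 461, without trend 137 and 489, robust 133 and 489, and with array weights 139 and 489. Genes lower stayed between 73.0% and 82.7% of the calls. Leaving out a library gave 368 to 403 higher and 1154 to 1237 lower genes.

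No shared effect of the replicate numbers was seen. Same-numbered WT and phod2 libraries had correlations of their deviations of -0.021, 0.0097 and -0.0078. Values near 0 cannot exclude a shared batch, because counting noise is a large part of these deviations. With the replicate block edgeR called 364 higher and 1153 lower genes, and limma on FPKM with the replicate block 138 and 490.

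The anthocyanin list passed in edgeR only with the preset correlation. Its adjusted p was 0.0784 with an estimated one, and by limma 0.268 at pseudocount 1 (the same without trend and robust), 0.266 at 0.1, 0.270 at 0.5, 0.390 without a filter, 0.391 at 0.1 FPKM, 0.0844 at 5 FPKM, 0.267 rescaled, 0.370 by median of ratios, 0.366 by TMM, 0.286 quantile normalized, 0.265 with weights and 0.305 with the replicate block. Carbon starvation lost its call at 0.0651 with an estimated correlation and by limma at 0.0578 (the same without trend and robust), 0.0725 at pseudocount 0.1, 0.0623 at 0.5, 0.158 at 5 FPKM, 0.0577 rescaled, 0.0607 quantile normalized, 0.0585 with weights and 0.0707 with the block. Root hair markers lost it at 0.0635 with an estimated correlation only, and had no value at 5 FPKM, where too few members were left, as had seed maturation markers and mitochondrion-encoded genes. Plastid-encoded genes lost it at 0.615 with an estimated correlation, 0.0636 in DESeq2 and 0.0575 at 5 FPKM, and iron homeostasis at 5 FPKM, at 0.109 in edgeR and 0.464 in limma. Seed maturation markers gained a call by limma at 0.0238 (the same without trend and robust), 0.0304 at pseudocount 0.1, 0.0259 at 0.5, 0.0250 rescaled, 0.0112 by median of ratios, 0.0104 by TMM, 0.0148 quantile normalized, 0.0246 with weights and 0.0197 with the block. The cause of these changes was not tested.

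Lists past the threshold in none of the fits run turned direction, and the cause was not tested. Mitochondrial lipoylated complexes turned at 0.858 in DESeq2, 0.923 on library totals and 0.998 by limma without a filter, with 0.773 to 0.974 over leave-one-out fits. The jasmonate list turned at 0.989 and 0.897 in edgeR at 1 and 5 FPKM, and by limma at 0.883 (also without trend and robust), 0.880, 0.884, 0.603, 0.888, 0.872, 0.877, 0.898, 0.884 and 0.899 with the block. Mitochondrion-encoded genes turned at 0.989 in edgeR at 1 FPKM, by limma at 0.520, 0.510, 0.515, 0.697, 0.930, 0.518, 0.608, 0.623, 0.524, 0.527 and 0.510 with the block, and over leave-one-out fits ranged from 0.433 to 0.994. The photosynthesis list turned at 0.945 on library totals, and the nitrate list at 0.919 and 0.903 by limma with median of ratios and TMM. PHR1 and NLA, past the threshold in none of the fits run, changed sign. PHR1 had log2 fold changes of 0.0247 on library totals and by limma 0.0218, 0.0225, 0.0222, 0.0216, 0.0238 and 0.0197, with -0.057 to 0.021 over leave-one-out fits. NLA had 0.0060 on library totals and by limma 0.0130, 0.0140, 0.0136, 0.0046 and 0.0116, with -0.091 to 0.031.

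Gene Ontology counts moved with the terms tested and the genes entered, from 8 higher terms to 2 with terms of 5 to 1000 genes, 4 at 1 FPKM, 5 at 5 FPKM, 5 by limma at pseudocount 0.1 and 47 on all genes past the adjusted p, with 5 to 9 over leave-one-out fits. Lower terms went from 51 to 28 and 27 at 5 FPKM in edgeR and limma and to 127 on all genes past the adjusted p. Over the 82 named genes, 2378 of 2436 alternative values kept direction and side of the threshold, 28 turned direction, all of them in PHR1 and NLA, 21 missed the threshold and 9 newly passed it. LEA76 accounts for all 9 of the last. The size of the fold moved by over 1.5 times toward 0 in at least 1 limma fit for 21 of 83 named genes, LIP1P included in the 83, and for 0 of them in the other alternatives that kept all libraries. AGP30 went from -5.06 to as little as -3.58, AT5G23840 from -4.63 to -2.57 and AT5G53048 from 4.55 to 2.86. SPX3 went from 2.68 to 0.93 and BCAT2 from 1.16 to 0.93, under 2-fold. For 8 higher terms 190 of 240 alternative values kept the call and 50 missed the threshold, and for 11 lower terms 316 of 318 kept it and 2 missed it. These are the first 8 in each direction by adjusted p and the xyloglucan:xyloglucosyl transferase, suberin and Casparian strip terms, of which the last 2 had no value at 5 FPKM. Extracellular region had none in 8 fits, where it held over 500 tested genes: at 0.1 FPKM and without a filter, in edgeR and limma, and without WT replicate 2, phod2 replicate 1, phod2 replicate 2 or phod2 replicate 3.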

Other observations

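All tests in this part except that of the root cap and meristem markers were chosen after the results were seen, and the genes of the first paragraph were picked after their values were known. The 4 genes looked up in the thalianol cluster on chromosome 5, whose neighbouring genes make a root triterpene, fell. THAS1 (positions 19456837 to 19461706) fell from 52.8 ± 1.44 to 7.95 ± 0.329 FPKM (SD, n = 3 each, log2 fold change -2.77 ± 0.05, SE), and CYP708A2, CYP705A5 and BAHD1 fell by 2.44, 2.82 and 3.30 on the log2 scale. The 3 genes looked up in the marneral cluster on the same chromosome fell as well, CYP71A16 (positions 17031024 to 17033800) going from 9.75 ± 0.243 to 1.13 ± 0.310 FPKM and CYP705A12 from 2.89 to 0.163 FPKM. MRN1, the first enzyme of that cluster, had 3.57 ± 0.373 FPKM in WT and 0.0333 ± 0.0306 FPKM in phod2. Of 8 measured suberin and barrier genes of the root 7 fell (median log2 fold change -0.99), from ABCG6 at -1.72 ± 0.10 to FAR4 at -0.76 ± 0.10 and ABCG20 at -0.73 ± 0.08, and ESB1 was at 0.65 ± 0.36 (adjusted p = 0.139), a gene covered over 84.6% by another.

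A set of 19 measured root hair, endodermis and stem cell markers had a median log2 fold change of -1.86, and 17 were lower past the adjusted p. SCR (0.10, adjusted p = 0.125) and SHR (0.07, adjusted p = 0.446) of the endodermis list, which did not fall, were left out of this set. The stem cell markers of that list were kept in it. The scalings tried did not account for the fall. The median was -1.82 on library totals and -1.86 with DESeq2 size factors. The value nearest to 0 over 5 scalings was -1.26, by limma on quantile normalized log2(FPKM + 1). Without rescaling limma gave -1.30 at a pseudocount of 1 and -1.80 at 0.1, so the pseudocount made most of that difference. The TMM factors were 0.985 to 1.017, so these scalings differed little and cannot speak to an error they share. A smaller share of root in the seedlings stays open, as the whole or a part of the pattern. Root cap and meristem markers had a median of -0.84 (5 measured genes of 8 listed, 3 past the adjusted p). This met, by a small margin, the prediction for a smaller share set before these genes were looked at. The genes are near the floor, at 0.43 to 1.04 FPKM in WT, with a median SE of 0.44. The SD of the markers' log2 fold changes was 3.95 times their median SE, which does not decide whether a smaller share is the only cause, because expression of the markers outside the root was not measured. Altered gene activity in roots of phod2 stays open and was not tested.

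Phosphate starvation genes and the iron uptake genes IRT1 and FRO2 rose while root markers fell. A larger share of root in phod2 with unchanged marker activity is argued against. It would raise the full root hair and endodermis lists, with SCR and SHR kept, whose medians were -1.59 and -1.86. The fall of these lists was already known when this explanation was weighed. These values cannot speak to a larger share joined with lowered marker activity, which was not tested. A phosphate supply that differed between the genotypes' plants stays open, because the labels of 0 of the 6 libraries name a supply, and it cannot be told apart from the genotype here. An effect of the mutation itself, the difference the design names, stays open as well and was not tested.

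Some genes known to be active in seedlings were at or near 0 counts in every library, among them MYC2 and LHCB1.5 with 0 counts and AMT1;1 with 18 in total. These lie largely within other genes, MYC2 over 98.5% of its length. Among coding genes of at least 500 bases, 48.4% of the 446 covered over 90% by other genes were at 0 in all libraries, against 9.98% of the 22564 covered under 10% (odds ratio 8.47), as would be seen if reads over overlapping genes were left out of the counts. Covered genes whose partner had over 50 counts in every library were at 0 a share 5.58 times that of uncovered genes. This cannot exclude absence of covered genes from seedlings, because their activity as a class was not measured otherwise. A candidate explanation for part of these genes is the counting step. However, AIR1, covered over 92.9%, had 661 to 898 counts in WT, and PSAG, covered over 61.4%, had 76996 in total. The gene covering LHCB1.5 had 0 counts in at least 1 library, which does not decide, because shared reads would be lost from both genes.

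Splits of the 6 libraries into 3 and 3 number 10, the real one included, too few for a share under 0.05. In 1 of the 10, the real split, the values were as large as the real ones. It gave 1515 called genes against at most 0 in the others by edgeR (1451 against 0 by DESeq2). It also gave 9172 genes past the adjusted p against 0, and 59 Gene Ontology terms against 0. Of gene lists it passed 8 against 1 to 6 in the others, by camera with the preset correlation. Groups in the other splits mix the genotypes unevenly, so the genotype difference adds to the spread within them. This lowers their counts of genes and terms, which therefore cannot serve as a measure of chance. The lists passed in these splits cannot tell false passes of camera from a remainder of the genotype difference. At an unadjusted p under 0.05 the other splits had 145 to 259 genes in edgeR, against 10390 for the real split.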
